A study of Mus musculus with 12 samples.

How the data were processed

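Total RNA from 12 samples of sorted mouse CD4+ T cells was measured on Affymetrix Mouse Gene 2.0 ST arrays, 1 array per sample. Per the labels, total splenic CD4+ cells came from 8-week-old Foxp3.eGFP reporter mice on the C57BL/6 background, whose regulatory T cells are marked by GFP. The cells were taken fresh (control) or cultured for 3 days, either with anti-CD3 and anti-CD28 antibodies (2 µg/ml of each) or with soluble OX40L (5 µg/ml) and JAG1 (1 µg/ml), and were then sorted into Foxp3+ Treg and Foxp3- Teff cells. This gives 6 groups of 2 arrays. Control cells were not cultured, so culture and treatment change together in every comparison with control. No label says that the replicates of a group are separate mice or cultures. The p-values therefore measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

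The deposited values are log2 summarised intensities that the authors made with RMA, whose version is not given in the sources used here. They were used as deposited. The table held 41345 rows. The probe table of the array gave at least 1 gene for 25335 rows and exactly 1 gene symbol for 23521. The 1814 rows with several symbols and the 16010 rows with none were left out of the main test. For the 1082 genes with several rows, the row with the highest mean over the 12 arrays was used, which left 22180 genes. Genes are named by the symbol in a gene table, matched by Entrez ID for 23328 rows, and otherwise by the symbol in the probe table. The gene table, also used to tell which genes lie inside others, is of the assembly GRCm38.p6. The build behind the array's annotation was not given in the sources used here, so no positions are printed.

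All tests used limma 3.58.1 in R 4.3.3. A model with 1 mean per group was fitted over all 12 arrays (6 residual degrees of freedom) and shrunk with eBayes. It gave 9 comparisons of 2 groups and 2 interactions, each the response of Treg cells minus the response of Teff cells. Adjusted p-values are Benjamini-Hochberg values within a comparison, two-sided, with a threshold of 0.05. Changes are on the log2 scale with their standard error (SE). The genes named are the 8 largest rises and the 8 largest falls of each comparison with an adjusted p under the threshold whose 2 arrays in one group both lie above both arrays of the other, the 5 largest in each direction for an interaction, up to 4 members of each list described, and Foxp3, Tnfrsf4, Notch1, Notch2, Notch3, Mki67 and Il2 throughout. Predicted genes, clone-named genes, small RNA genes with numbered family names, olfactory and vomeronasal receptors, and immunoglobulin and T cell receptor segments were not named.

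The lists hold 412 genes in 22 groups, of which 370 were measured. They cover the Treg signature, resting T cell genes, cell cycle, T cell activation, the IL-2 and STAT5 response, effector cytokines, chemokines and receptors, cytotoxic mediators, coinhibitory receptors, T helper transcription factors, the Notch pathway, the NF-kappaB and TNF receptor pathway, glycolysis, cholesterol synthesis, the amino acid and integrated stress response, the interferon response, apoptosis regulators, T cell identity, and markers of B cells, of myeloid and dendritic cells, of CD8 T and NK cells, and of erythroid cells and platelets. Each was tested against all other genes with camera at a preset inter-gene correlation of 0.01, two-sided, adjusted over the 22 lists of a comparison. Camera was also run with an estimated correlation, and fry was run as another set test. The comparisons, the lists, the rule for named genes and the main alternatives were fixed before the data were examined. Further gene groups (neutrophil, basophil and mast cell, heat shock and immediate early, hypoxia, fatty acid, Y-linked and X-linked partner genes, small nucleolar RNA genes, immunoglobulin segments and histone genes) were put together after the data were seen and are described as such.

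The alternatives chosen then were the replicate set as a block, dim genes left out, a trend and robust shrinkage, quantile normalization over the tested genes, scaling to a common median, array weights, the mean of all rows of a gene, all rows, only the 4 arrays of the groups compared, a change of at least 1 on the log2 scale, each array left out in turn, the estimated correlation and fry. After the data were seen, 3 more were added: the OX40L-JAG1 Teff arrays left out, the trend of the change with level removed by loess, and small RNA, segment and sex-linked genes left out. The differences between replicates of the 6 groups gave 15 correlations, from -0.0693 to 0.182, the highest between OX40L-JAG1 Treg and OX40L-JAG1 Teff cells. They show no strong effect shared by a replicate set, but cannot show that samples are unpaired. The replicate block is used only as an alternative.

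The procedure was tested on simulated data with the same groups and spreads and 22180 genes, 100 of them changed at each size. Of the changes of 2 on the log2 scale, 83 to 93% were recovered, and of those of 1, 7 to 48%. The simulation gave at most 1 false call in comparisons without the OX40L-JAG1 Teff arrays, but 229, 508 and 343 in the comparisons of those arrays with control Teff, anti-CD3-CD28 Teff and OX40L-JAG1 Treg cells. With array weights these fell to 1, 6 and 5, and 54, 52 and 52% of the changes of 2 were recovered, while the other comparisons had 6 to 15 false calls. Camera called the shifted list in each of 9 comparisons and none of the 21 others. The simulated genes varied independently of each other, so this does not test the list calls under correlation between genes. No trend of the change with level was simulated either.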

Results

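The transcriptomes of Foxp3+ regulatory (Treg) and Foxp3- effector (Teff) CD4+ T cells of the mouse spleen were measured fresh (control) and after 3 days with anti-CD3 and anti-CD28 antibodies, which act through the T cell receptor, or with the soluble ligands OX40L and JAG1, of the receptor OX40 and of Notch, which do not. The series asks how expansion that depends on the T cell receptor differs from expansion that does not. Each of the 6 groups had 2 arrays. Foxp3 served as the label check, since its reporter defined the sort. Its mean log2 intensity was 10.37, 10.78 and 11.12 in control, OX40L-JAG1 and anti-CD3-CD28 Treg cells and 5.66, 6.58 and 5.65 in the matching Teff cells.

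The OX40L-JAG1 Teff arrays stood apart from the others. The SD over genes was 1.49 in their replicate B and 1.71 in replicate 1, against 1.95 to 2.19 in the other 10 arrays. The correlation between the replicates across genes was 0.881, against 0.984 to 0.994 in the other groups, and the SD of their difference was 0.81, against 0.234 to 0.362. Array weights, which measure how well an array follows its group, were 0.169 for them and 0.911 to 2.34 for the rest. These arrays widen the pooled spread used for every comparison, so counts without them are given beside the main ones. The first principal component held 46.6% of the variance and the next 17%. The deposited values carry no detection call. A group mean below the lowest array median (4.87) is not shown to be above background, so a change to or from it is read as a lower bound. This holds for 62 of the 144 largest changes named in the comparisons of 2 groups. In the interactions a group mean lies below it for 5 of the 5 genes with the most positive differences for OX40L-JAG1 and 2 of the 5 for anti-CD3-CD28. This bound was chosen after the results were seen.

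**Figure D1:**
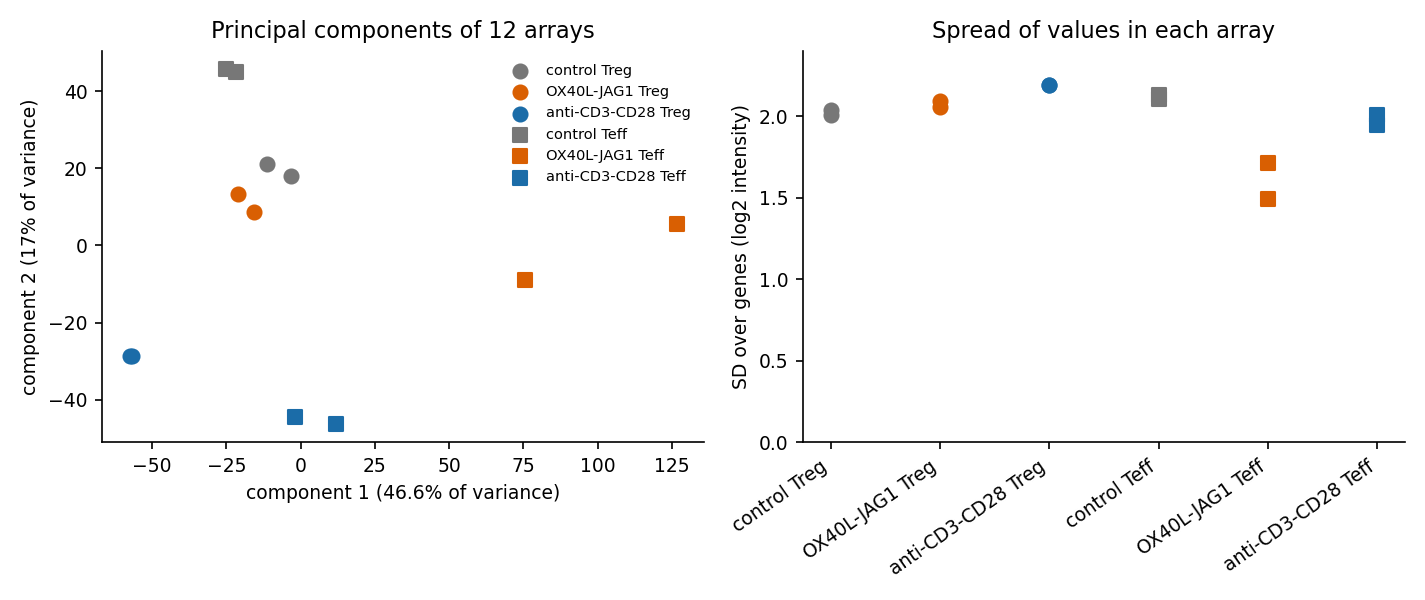
Left, the 12 arrays on their first 2 principal components, with 46.6% and 17% of the variance on the axes, and right, the SD of log2 intensity over 22180 genes in each array, with 1 point per array, colored by treatment, circles for Treg and squares for Teff cells. The OX40L-JAG1 Teff arrays lie at the far right of component 1 and have SDs of 1.49 and 1.71.

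Control Treg and control Teff cells were compared before culture. Foxp3 was 26-fold higher in control Treg cells (log2 10.37 ± 0.013 against 5.66 ± 0.001, SD, n = 2 each, adjusted p = 9.85e-07). Among the other genes, Lrrc32, which holds latent TGF-beta at the cell surface, was higher by 4.95 ± 0.23 (log2, SE), Il2ra, a chain of the IL-2 receptor, by 4.45 ± 0.27, and Klrg1 by 4.29 ± 0.27. Tnfrsf4, which encodes OX40, was higher by 3.54 ± 0.25, Rgs1 by 3.47 ± 0.31, the inhibitory receptor Ctla4 by 3.45 ± 0.23 and Gbp2b by 3.41 ± 0.39, with adjusted p from 9.85e-07 to 0.00059. Control Teff cells had more of the carbonic anhydrases Car1 (-4.68 ± 0.40) and Car2 (-4.34 ± 0.53), of Atp8b4 (-4.64 ± 0.29), Pde3b (-4.40 ± 0.30), Ces2g (-3.37 ± 0.32), Mctp2 (-3.34 ± 0.43) and Vipr1 (-3.21 ± 0.17), and of Jchain (-4.20 ± 0.47), which joins antibody chains, with adjusted p from 2.69e-06 to 0.00116. Car2 is also in the list of erythroid and platelet markers, of which 1 of 6 was lower (1 adjusted over the list alone, camera adjusted p = 0.109).

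Of the 28 measured Treg signature genes, 27 were higher in control Treg cells and 28 when adjusted over the list alone (camera adjusted p = 2.88e-57; adjusted p = 0.0132 with an estimated correlation). Coinhibitory receptors were higher in 5 of 12 (8 adjusted over the list alone, adjusted p = 3.18e-09, and 0.0316 with an estimated correlation), with Tigit at 2.38 ± 0.29, Entpd1 at 1.99 ± 0.21 and Pdcd1 at 1.29 ± 0.28. Resting T cell genes were lower in 9 of 18 (15 adjusted over the list alone, adjusted p = 3.12e-14), among them Igfbp4 (-2.52 ± 0.33), Actn1 (-1.75 ± 0.18) and Satb1 (-1.53 ± 0.18). That call had adjusted p = 0.123 with an estimated correlation. In these 2 lists 9 coinhibitory receptors were higher and 14 resting T cell genes lower without the OX40L-JAG1 Teff arrays. B cell markers were lower in 7 of 15 (9 adjusted over the list alone, adjusted p = 1.51e-10, and 0.017 with an estimated correlation), with H2-Ab1 at -2.80 ± 0.33, Cd79a at -2.04 ± 0.25 and Ms4a1 at -1.89 ± 0.25, and immunoglobulin segments were lower in 19 of 19. The myeloid marker S100a8 was also lower, by -1.68 ± 0.37 (adjusted p = 0.0295). CD8 T and NK cell markers were lower in 1 of 10, Klrd1 (-3.10 ± 0.56; 3 adjusted over the list alone, adjusted p = 0.00727, and 0.313 with an estimated correlation). Of the groups put together after the data were seen, 5 of 14 neutrophil genes were lower (8 without the OX40L-JAG1 Teff arrays) and 1 higher, 2 of 11 basophil and mast cell genes lower (4 without them), and 32 of 73 small nucleolar RNA genes higher and 1 lower. In the IL-2 and STAT5 response 4 of 16 were higher (6 higher and 2 lower adjusted over the list alone, adjusted p = 0.0452, and 0.439 with an estimated correlation), although its median change was -0.00652 and its mean 0.607. No cell cycle gene passed in limma in this comparison (2 higher and 2 lower at an unadjusted p under 0.05). Mki67, a marker of cycling cells, had 0.33 ± 0.39 (adjusted p = 0.778). Notch1 (-0.28 ± 0.19, adjusted p = 0.521), Notch2 (-0.25 ± 0.20, 0.631) and Notch3 (0.18 ± 0.38, 0.897) did not pass either. In all, 297 genes were higher and 556 lower in control Treg cells (853, and 3220 without the OX40L-JAG1 Teff arrays). The share that was higher was 34.8%, against 49.1% after quantile normalization. Leaving out 1 array gave between 248 genes (without control Teff replicate B) and 3220 (without OX40L-JAG1 Teff replicate B).

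**Figure D2:**
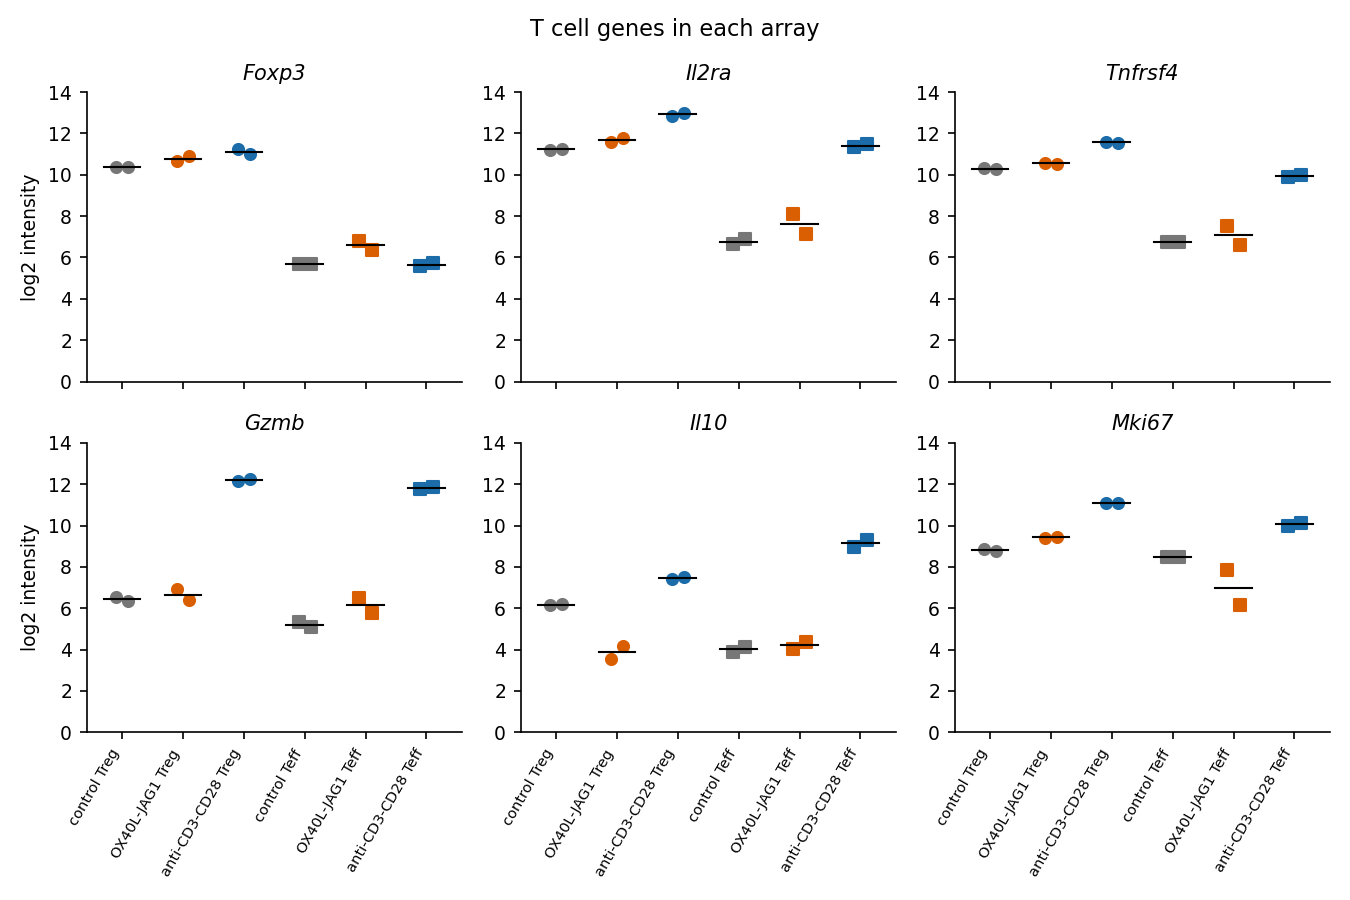
Log2 intensity of 6 T cell genes in each of 12 arrays, with points for arrays, lines for means of 2 arrays and colors for treatments. Foxp3 lies between 10.37 and 11.12 on average in the Treg groups and between 5.65 and 6.58 in the Teff groups, and Gzmb averages 12.21 and 11.81 in anti-CD3-CD28 Treg and Teff cells and at most 6.66 in the other groups.

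OX40L-JAG1 Treg and control Treg cells were compared for the effect of the ligands in culture. The largest rises were of transcripts abundant in granulocytes, basophils and platelets. S100a8, part of the neutrophil protein calprotectin, was higher (log2 9.75 ± 0.13 against 3.48 ± 0.15, SD, n = 2 each, adjusted p = 2.93e-05), and S100a9 rose by 4.12 ± 0.33 (SE), Chil3 by 5.02 ± 0.54, the basophil protease Mcpt8 by 4.73 ± 0.28. Lysozyme Lyz2 rose by 4.39 ± 0.38, the mast cell protease Cpa3 by 4.18 ± 0.38, the platelet chemokine Ppbp by 4.16 ± 0.49 and the MHC class II gene H2-Ab1 by 3.72 ± 0.33. Falls were led by the heat shock genes Hspa1a (-3.54 ± 0.23, adjusted p = 4.59e-05) and Hspa1b (-3.34 ± 0.38), followed by Gsta4 (-2.68 ± 0.18), the anti-inflammatory cytokine Il10 (-2.31 ± 0.25), Snhg17 (-2.27 ± 0.27), Rabggtb (-2.12 ± 0.29), Dtx1, a target of Notch signalling (-2.11 ± 0.20), and Rps20 (-2.05 ± 0.37). Adjusted p of these 16 genes lay at or below 0.0199. Small nucleolar RNA genes moved with Snhg17, Rabggtb and Rps20: 29 of 73 fell (51 without the OX40L-JAG1 Teff arrays). Foxp3 (0.41 ± 0.21, adjusted p = 0.566) and Tnfrsf4 (0.25 ± 0.25, 0.885) did not pass, nor did Notch1 (-0.13 ± 0.19, 0.947), Notch2 (0.40 ± 0.20, 0.576), Notch3 (-0.10 ± 0.38, 0.988) or Il2 (0.42 ± 0.22, 0.588).

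Metabolic lists rose in OX40L-JAG1 Treg cells. In glycolysis 8 of 17 rose (14 adjusted over the list alone, camera adjusted p = 3.99e-20, and 0.0418 with an estimated correlation). Examples were Tpi1 at 1.64 ± 0.23, Hif1a at 1.39 ± 0.24 and Pgk1 at 1.2 ± 0.19. In cholesterol synthesis 4 of 14 rose (10 adjusted over the list alone, adjusted p = 7.2e-12, and 0.0418 with an estimated correlation), with Hmgcs1 at 2.03 ± 0.29 and Cyp51 at 1.77 ± 0.34. Myeloid and dendritic cell markers rose in 6 of 19 (10 adjusted over the list alone, adjusted p = 3.2e-12, and 0.0418 with an estimated correlation) and erythroid and platelet markers in 2 of 6, Ppbp and Pf4 (2 adjusted over the list alone, adjusted p = 0.000172, and 0.0418 with an estimated correlation). T cell activation genes fell in 3 of 24 and rose in 1 (12 fell and 1 rose adjusted over the list alone, adjusted p = 1.13e-06, and 0.156 with an estimated correlation). Those that fell were Egr1 (-1.62 ± 0.27), Nr4a1 (-1.43 ± 0.20) and Egr3 (-0.96 ± 0.21), which are induced within hours of receptor signalling. Bhlhe40 rose (1.96 ± 0.22). Of the coinhibitory receptors, Lag3 (-1.44 ± 0.19) and Tigit (-1.38 ± 0.29) fell among 12 (3 adjusted over the list alone, adjusted p = 0.000197, and 0.103 with an estimated correlation). In the NF-kappaB and TNF receptor pathway, which OX40 engages, 1 of 21 rose, Nfkb2 (1.36 ± 0.17; 6 adjusted over the list alone, adjusted p = 6.44e-06, and 0.184 with an estimated correlation). The Treg signature had 2 rises, Itgae (1.92 ± 0.18) and Socs2 (1.83 ± 0.34), and 6 falls among 28 (4 and 11 adjusted over the list alone, adjusted p = 0.112), with a median of 0.129 and a mean of -0.209. In the Notch pathway 1 of 25 fell, Dtx1 (1 adjusted over the list alone, adjusted p = 0.609). In the fit without the OX40L-JAG1 Teff arrays 9 cholesterol synthesis genes, 10 myeloid and dendritic cell markers and 5 NF-kappaB and TNF receptor genes rose, and 9 T cell activation genes, 5 coinhibitory receptors and 10 Treg signature genes fell.

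No cell cycle gene among 30 passed in limma in OX40L-JAG1 Treg cells (9 higher and 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.0296, and 0.669 with an estimated correlation). Without the OX40L-JAG1 Teff arrays 7 rose and 1 fell. Mki67 was higher by 0.63 ± 0.39 (adjusted p = 0.715, and 0.0236 without those arrays). Over all genes, 221 rose and 124 fell (345, and 1200 without the OX40L-JAG1 Teff arrays). With 1 array left out the count lay between 99 genes (without OX40L-JAG1 Treg replicate B) and 1200 (without OX40L-JAG1 Teff replicate B).

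**Figure D3:**
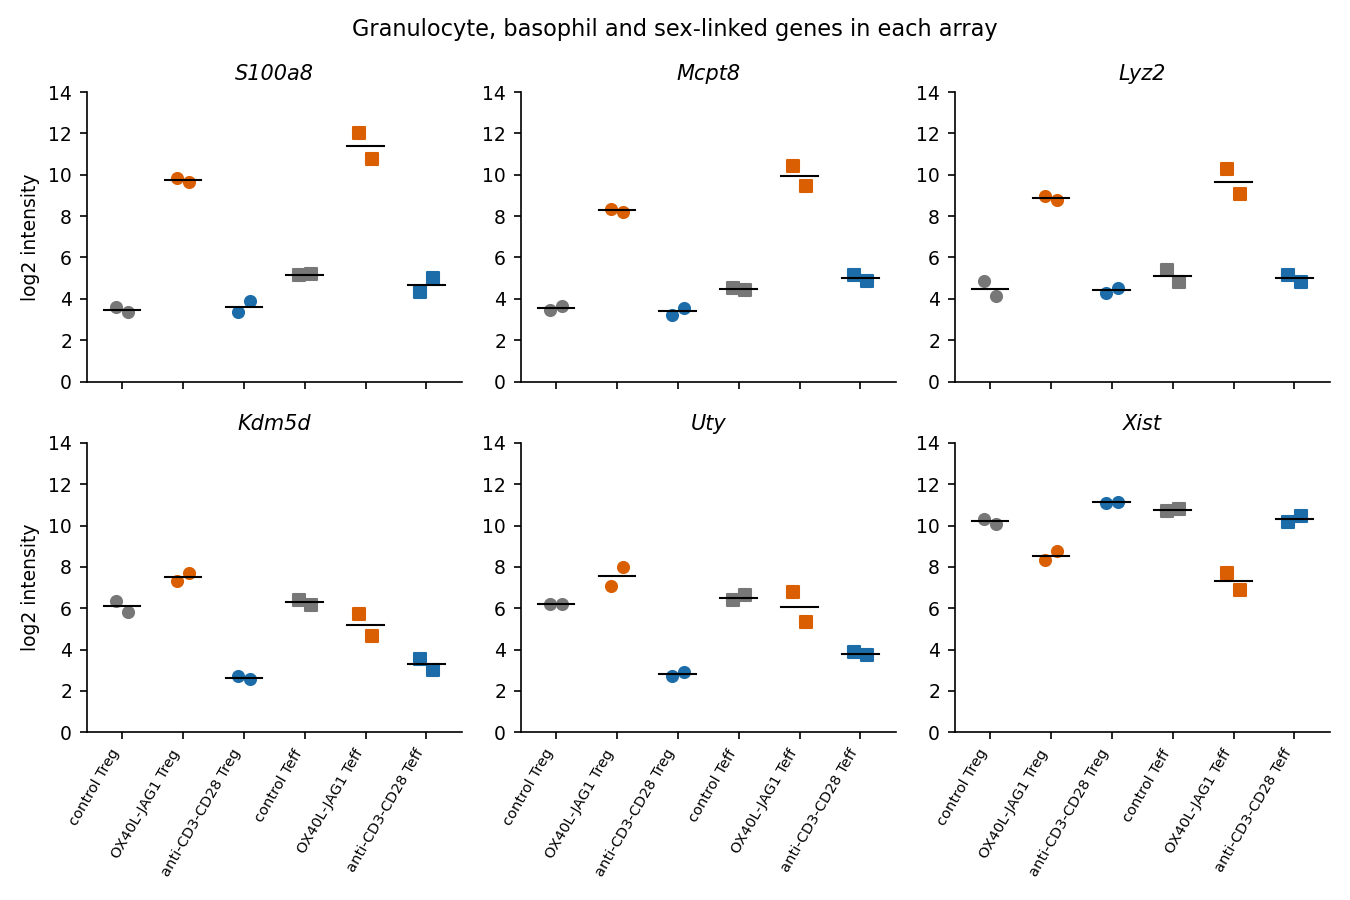
Log2 intensity of the neutrophil and myeloid genes S100a8 and Lyz2, the basophil gene Mcpt8, the Y-linked genes Kdm5d and Uty, and Xist in each of 12 arrays, with points for arrays and lines for means of 2. S100a8 averages 9.75 and 11.4 in the OX40L-JAG1 groups and at most 5.16 in the others, and Kdm5d averages 2.65 and 3.28 in the anti-CD3-CD28 groups and at least 5.19 in the others.

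Anti-CD3-CD28 Treg and control Treg cells were compared for the response to the T cell receptor. Gzma, a granzyme of cytotoxic granules, was higher (log2 11.40 ± 0.10 against 4.36 ± 0.30, SD, n = 2 each, adjusted p = 4.18e-05), and Gzmb was 54.5-fold higher (12.21 ± 0.08 against 6.45 ± 0.12, 8.98e-07). The IL-12 receptor gene Il12rb2 rose by 6.51 ± 0.28 (SE), the fatty acid desaturases Scd1 and Fads2 by 5.59 ± 0.31 and 5.10 ± 0.38. Cyp11a1, the first enzyme of steroid hormone synthesis, rose by 5.49 ± 0.27, the oxygen sensor Egln3 by 4.81 ± 0.29 and Efna5 by 4.36 ± 0.24. The heat shock genes Hspa1a (-7.50 ± 0.23, adjusted p = 5.33e-08) and Hspa1b (-6.81 ± 0.38) had the largest measured falls, to 3.38 and 4.45, below the array medians, then Ptcd3 (-3.77 ± 0.28), Rps20 (-3.57 ± 0.37), Wdyhv1 (-3.46 ± 0.31), the Y-linked Kdm5d (-3.44 ± 0.34) and Uty (-3.41 ± 0.40), and Gsta4 (-3.24 ± 0.18). Small nucleolar RNA genes moved with Ptcd3 and Rps20, with 65 of 73 lower. Foxp3 rose by 0.75 ± 0.21 (adjusted p = 0.0405), Tnfrsf4 by 1.27 ± 0.25 (0.00728), Mki67 by 2.30 ± 0.39 (0.00288) and Notch1 by 0.66 ± 0.19 (0.0453). Notch1 had 0.28 after quantile normalization and 0.35 with the level trend removed, where Foxp3 had 0.45. Notch2 (0.05 ± 0.20, 0.918), Notch3 (-0.33 ± 0.38, 0.691) and Il2 (-0.18 ± 0.22, 0.714) did not pass.

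In anti-CD3-CD28 Treg cells, cell cycle genes rose in 28 of 30 (29 adjusted over the list alone, camera adjusted p = 5.39e-30, and 0.0322 with an estimated correlation), with Bub1 at 3.51 ± 0.31, Kif11 at 2.79 ± 0.28 and Plk1 at 2.76 ± 0.19. Glycolysis rose in 17 of 17 (17 adjusted over the list alone, 3.9e-27, and 0.0272 with an estimated correlation), with Slc16a3 at 3.26 ± 0.19 and the glucose transporter Slc2a1 at 3.13 ± 0.21. Cholesterol synthesis rose in 13 of 14 (14 adjusted over the list alone, 6.37e-17, and 0.0272 with an estimated correlation), with Hmgcs1 at 3.34 ± 0.29 and Sqle at 2.86 ± 0.37. The IL-2 and STAT5 response rose in 13 of 16 (13 adjusted over the list alone, 1.2e-13, and 0.0272 with an estimated correlation), with Socs2 at 2.81 ± 0.34 and Il2ra at 1.71 ± 0.27. Other calls did not hold with an estimated correlation. The interferon response rose in 14 of 21 (16 adjusted over the list alone, adjusted p = 1.99e-12, and 0.202 with an estimated correlation), with Stat2 at 2.36 ± 0.26. T helper transcription factors rose in 10 of 16 (13 rose and 1 fell adjusted over the list alone, 1.7e-07, and 0.0885 with an estimated correlation), with Runx3 at 2.18 ± 0.25. The amino acid and integrated stress response rose in 8 of 18 (10 adjusted over the list alone, 5.92e-07, and 0.185 with an estimated correlation), with Asns at 2.10 ± 0.20. After quantile normalization these 3 lists had 9, 5 and 3 rises. In the Treg signature 14 rose and 4 fell (15 and 7 adjusted over the list alone, 0.00311, and 0.447 with an estimated correlation). Tnfrsf9 rose by 2.48 ± 0.18, and Nrp1 (-2.14 ± 0.25) and Cd83 (-2.08 ± 0.23) fell.

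Of the remaining lists in this comparison, cytotoxic mediators had 6 rises and 1 fall among 14 (7 and 2 adjusted over the list alone, camera adjusted p = 0.0106, and 0.447 with an estimated correlation), apoptosis regulators 3 rises among 16 (3 adjusted over the list alone, 0.00977, and 0.447 with an estimated correlation), led by Cdkn1a (3.68 ± 0.22), which arrests the cell cycle. The NF-kappaB and TNF receptor pathway had 3 among 21 (4 adjusted over the list alone, 0.0155, and 0.462 with an estimated correlation). Camera did not call effector cytokines (6 rises and 2 falls among 21, the same adjusted over the list alone, adjusted p = 0.057), coinhibitory receptors (5 and 3 among 12, 5 and 4 adjusted over the list alone, 0.323) or chemokines and receptors (5 and 2 among 19, 6 and 3 adjusted over the list alone, 0.756). Nor did it call T cell activation (9 and 4 among 24, 9 and 6 adjusted over the list alone, 0.459), resting T cell genes (2 and 6 among 18, 4 and 6 adjusted over the list alone, 0.211) or the Notch pathway (5 and 2 among 25, 6 and 3 adjusted over the list alone, 0.756), in which Jag1 rose (1.2 ± 0.23) and Dtx1 fell (-2.52 ± 0.20). T cell identity had 2 rises among 12 (2 adjusted over the list alone, 0.421). Markers of other cells were not called either. B cells had 1 rise, H2-Ab1 (4.24 ± 0.33), and 1 fall, Jchain (-1.97 ± 0.47), among 15 (the same adjusted over the list alone, 0.141), and myeloid and dendritic cells 1 and 2 among 19 (2 and 4 adjusted over the list alone, 0.323). CD8 T and NK cells had 1 rise among 10, Gzma (1 adjusted over the list alone, 0.449), and erythroid cells and platelets 1 among 6, Ppbp (2 adjusted over the list alone, 0.323). Over all genes 1792 rose and 438 fell (2230, and 4770 without the OX40L-JAG1 Teff arrays). The share that rose was 80.4%, against 65.8% after quantile normalization. Leaving out 1 array gave between 1054 genes (without anti-CD3-CD28 Treg replicate 1) and 4770 (without OX40L-JAG1 Teff replicate B).

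**Figure D4:**
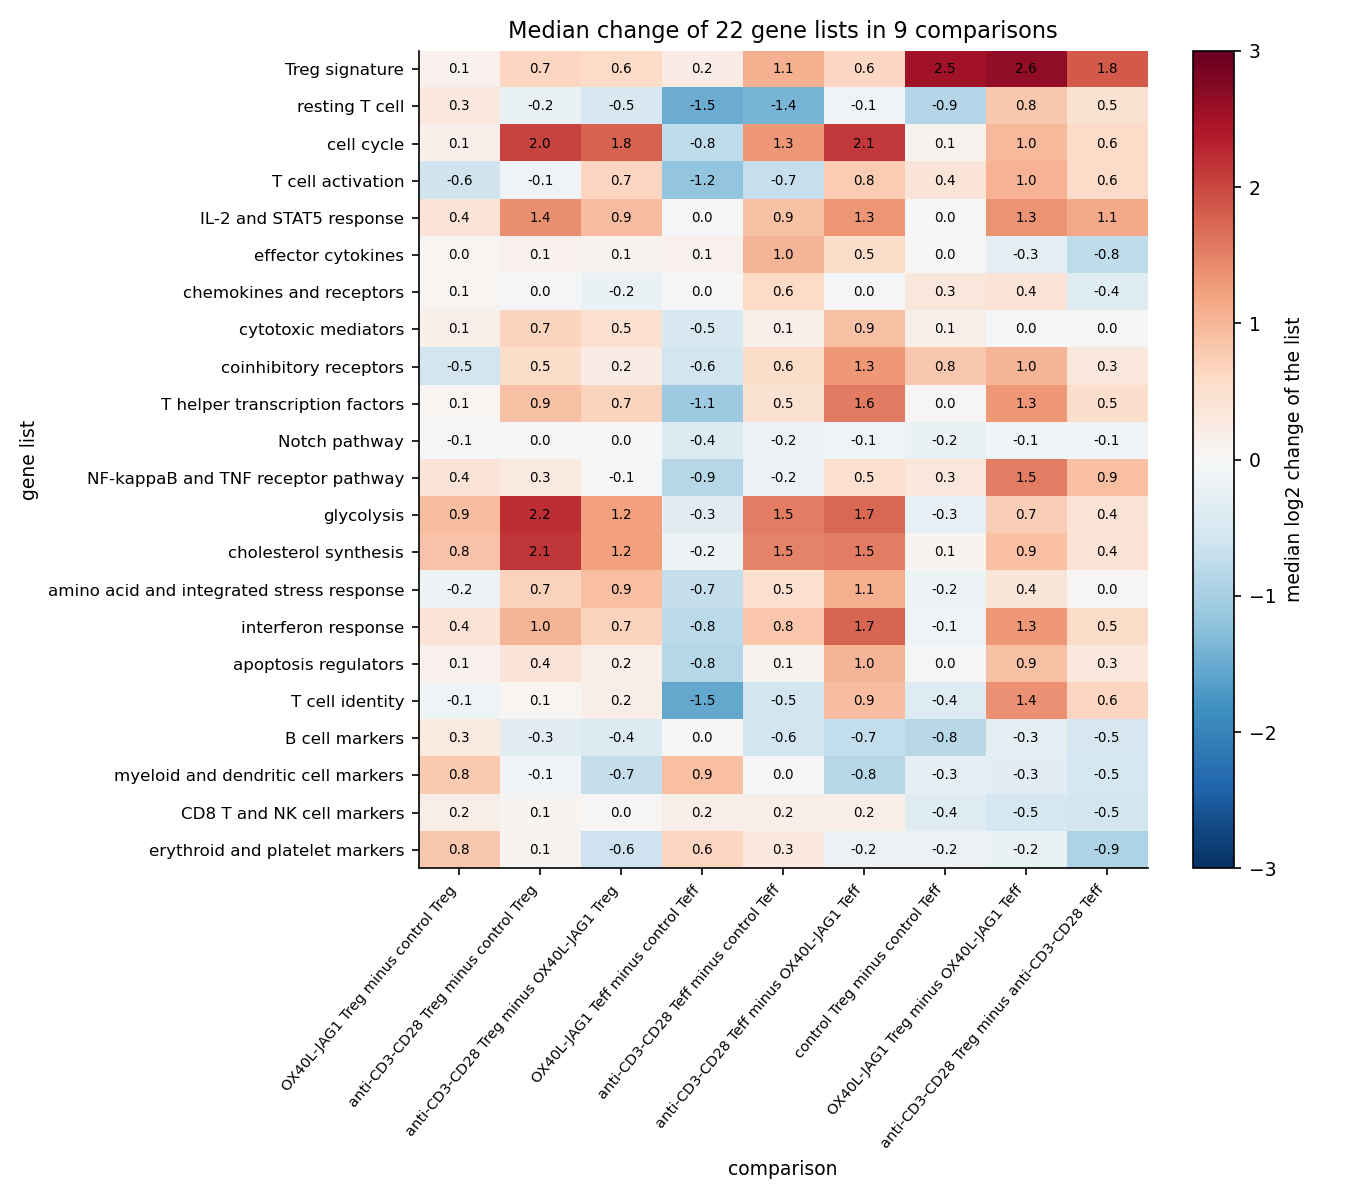
Median log2 change (color and printed value, to 1 decimal) of each of 22 gene lists, on the vertical axis, in the 9 comparisons of 2 groups, on the horizontal axis, with red for higher and blue for lower values in the first group named. Glycolysis has medians of 0.925 in OX40L-JAG1 Treg and 2.21 in anti-CD3-CD28 Treg cells against control Treg cells.

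Anti-CD3-CD28 Treg and OX40L-JAG1 Treg cells set the expansion methods side by side in cultured cells. Granzymes were higher with anti-CD3-CD28: Gzma by 5.56 ± 0.65 (log2, SE, adjusted p = 0.000411) and Gzmb 46.9-fold (12.21 ± 0.08 against 6.66 ± 0.35, SD, n = 2 each, 4e-06). So were Tnfrsf8, which encodes CD30 (4.80 ± 0.25), and Il12rb2 (4.45 ± 0.28). Also higher were Ermn (4.27 ± 0.32), Cyp11a1 (4.03 ± 0.27), Egln3 (3.76 ± 0.29), the transcription factor Nfil3 (3.73 ± 0.21) and Il10 (3.60 ± 0.25). Granulocyte and basophil genes were lower, S100a8 by -6.13 ± 0.37 (7.45e-06), Chil3 by -5.01 ± 0.54, Mcpt8 by -4.88 ± 0.28, Lyz2 by -4.48 ± 0.38 and Ngp by -4.20 ± 0.22, as were the Y-linked Eif2s3y (-5.08 ± 0.36), Kdm5d (-4.85 ± 0.34) and Uty (-4.74 ± 0.40). Mki67 was higher by 1.67 ± 0.39 (0.028), Tnfrsf4 by 1.02 ± 0.25 (0.0362) and Notch1 by 0.79 ± 0.19 (0.0282). Foxp3 (0.34 ± 0.21, 0.526), Notch2 (-0.34 ± 0.20, 0.499), Notch3 (-0.24 ± 0.38, 0.882) and Il2 (-0.60 ± 0.22, 0.171, and 0.0414 with array weights) did not pass.

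Cell cycle genes were higher with anti-CD3-CD28 in 26 of 30 (30 adjusted over the list alone, camera adjusted p = 1.85e-37, and 0.0336 with an estimated correlation), such as Bub1 (2.53 ± 0.31), Ccna2 (2.34 ± 0.30) and Rrm2 (2.28 ± 0.31). Glycolysis was higher in 14 of 17 (17 adjusted over the list alone, 5.19e-22, and 0.0336 with an estimated correlation), with Slc16a3 at 2.27 ± 0.19 and Hk2 at 2.07 ± 0.23. Cholesterol synthesis was higher in 7 of 14 (12 adjusted over the list alone, 1.28e-11, and 0.0336 with an estimated correlation), with Lss at 2.21 ± 0.24. The IL-2 and STAT5 response was higher in 8 of 16 (13 higher and 1 lower adjusted over the list alone, 5.77e-11, and 0.0336 with an estimated correlation), with Lif at 2.23 ± 0.20 and Socs3 at 1.98 ± 0.22. Myeloid and dendritic cell markers were lower in 8 of 19 (13 adjusted over the list alone, 1.4e-14, and 0.0336 with an estimated correlation) and B cell markers in 3 of 15 (5 adjusted over the list alone, 8.89e-06, and 0.0348 with an estimated correlation), namely H2-Aa (-2.97 ± 0.33), H2-Eb1 (-1.93 ± 0.37) and Bank1 (-1.63 ± 0.24). Coinhibitory receptors were higher in 5 and lower in 2 of 12 (the same adjusted over the list alone, 0.0103, and 0.158 with an estimated correlation), with Havcr2 at 3.19 ± 0.26, Tigit at 2.74 ± 0.29 and Lag3 at 2.58 ± 0.19. The NF-kappaB and TNF receptor pathway was not called (4 higher, 2 lower of 21, 4 and 6 adjusted over the list alone, 0.317). Bcl3 was higher (1.30 ± 0.29) and Nfkb2 lower (-1 ± 0.17). Counts without the OX40L-JAG1 Teff arrays were 13 higher genes each for cholesterol synthesis and the IL-2 and STAT5 response and 6 lower B cell markers. Over all genes 1050 were higher and 261 lower (1311, and 3082 without the OX40L-JAG1 Teff arrays). The share that was higher was 80.1%, against 66.2% after quantile normalization. With 1 array left out the count lay between 595 genes (without anti-CD3-CD28 Treg replicate B) and 3082 (without OX40L-JAG1 Teff replicate B).

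OX40L-JAG1 Teff and control Teff cells were compared for the effect of the ligands in culture on effector cells. As in Treg cells, granulocyte and basophil transcripts led the rises. S100a8 was 75.7-fold higher (log2 11.4 ± 0.89 against 5.16 ± 0.028, SD, n = 2 each, adjusted p = 7.92e-06), Chil3 rose by 5.67 ± 0.54 (SE), S100a9 by 5.50 ± 0.33 and Mcpt8 by 5.49 ± 0.28. The granule proteins Ngp and Camp rose by 4.64 ± 0.22 and 4.44 ± 0.57, Lyz2 by 4.56 ± 0.38 and the receptor Lilrb4a by 4.48 ± 0.32. With array weights the adjusted p of these 8 genes lay between 8.88e-06 and 0.000737. The falls were led by Hspa1b (-4.18 ± 0.38), Car1 (-4.07 ± 0.40), Hspa1a (-3.77 ± 0.23), the interferon-inducible Ifi208 (-3.76 ± 0.39), Jchain (-3.53 ± 0.47), Xist (-3.45 ± 0.27), Ehd3 (-3.36 ± 0.25) and Jun (-3.18 ± 0.24), with adjusted p from 3.98e-05 to 0.00178 with array weights. Immunoglobulin segments fell with Jchain in 19 of 19. Notch1 (-1.31 ± 0.19, 0.000286), Notch2 (-1.29 ± 0.20, 0.000489) and Mki67 (-1.47 ± 0.39, 0.0108) fell. After quantile normalization they had -0.26, -0.27 and -0.62, and with the level trend removed -0.08, -0.14 and -0.21. Foxp3 rose by 0.92 ± 0.21 (0.00448, and 0.064 with array weights), and by 1.62 and 2.15 under these settings. Tnfrsf4 (0.31 ± 0.25, 0.316), Notch3 (0.61 ± 0.38, 0.201) and Il2 (0.32 ± 0.22, 0.231) did not pass. Tnfrsf4 had 1.26 and Il2 -0.19 after quantile normalization, and 1.58 and -0.25 with the level trend removed, so their size depends on the scaling.

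Lists in this comparison moved with the narrow range of the OX40L-JAG1 Teff arrays: across genes, the change correlated with the mean level at -0.651, and genes are not independent replicates. T cell identity genes fell in 11 of 12 (11 adjusted over the list alone, camera adjusted p = 1.76e-06, and 0.296 with an estimated correlation), with Cd4 at -2.55 ± 0.22, Cd6 at -2.17 ± 0.21 and Cd3e at -2.13 ± 0.18. In that list 11 also fell with array weights. Resting T cell genes fell in 15 of 18 (17 adjusted over the list alone, 2.51e-07, and 0.296 with an estimated correlation), such as Igfbp4 (-2.81 ± 0.33) and Foxo1 (-2.63 ± 0.18). T cell activation genes fell in 17 of 24 and rose in 1 (18 and 2 adjusted over the list alone, 4.81e-05, and 0.296 with an estimated correlation). The NF-kappaB and TNF receptor pathway fell in 16 of 21 (16 adjusted over the list alone, 5.61e-05, and 0.312 with an estimated correlation), with Rel at -1.84 ± 0.21 and Rela at -1.77 ± 0.19. Cell cycle genes fell in 16 of 30 (18 adjusted over the list alone, 9.69e-05, and 0.465 with an estimated correlation), 8 of them with array weights. Myeloid and dendritic cell markers rose in 13 of 19 (13 adjusted over the list alone, 5.6e-06, and 0.296 with an estimated correlation), 8 with array weights. In the order given, the first 5 lists had 7, 9, 9, 4 and 7 falls after quantile normalization and 5, 4, 8, 0 and 1 with the level trend removed, so these falls depend on the scaling, while 14 and 11 myeloid and dendritic cell markers rose. Over all genes 4441 rose and 5964 fell (10405). Array weights gave 819 rises and 3869 falls (4688), and removing the trend of the change with level 1476 rises and 1572 falls (3048). The share that rose was 42.7%, against 22.3% with arrays scaled to a common median. The median over all genes was 0.177 and moved to -0.0576 with that scaling and to -0.00315 after quantile normalization. Leaving out 1 array gave between 6129 genes (without control Teff replicate B) and 13691 (without OX40L-JAG1 Teff replicate 1).

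Anti-CD3-CD28 Teff and control Teff cells were compared for the response of effector cells to the T cell receptor. Gzmb was 96.9-fold higher (log2 11.81 ± 0.08 against 5.21 ± 0.15, SD, n = 2 each, adjusted p = 2.06e-07) and Gzma was higher too (11.26 ± 0.06 against 4.87 ± 0.18, 9.92e-05). Ifi204 rose by 5.69 ± 0.24 (SE), Il10 by 5.12 ± 0.25, the leukotriene receptor Cysltr1 by 4.95 ± 0.27, and Il2ra by 4.64 ± 0.27. The type 2 cytokine Il13 rose by 4.55 ± 0.34, Pros1 by 4.22 ± 0.25 and Tnfrsf4 by 3.20 ± 0.25 (1.75e-05). Hspa1b (-8.41 ± 0.38, 6.35e-07) and Hspa1a (-7.96 ± 0.23, 2.76e-08) had the largest measured falls, to 3.84 and 3.65, below the array medians, then Jchain (-4.86 ± 0.47), the monocarboxylate transporter Slc16a5 (-3.57 ± 0.31), Atp1b1 (-3.48 ± 0.21), Ehd3 (-3.43 ± 0.25), Actn1 (-3.43 ± 0.18) and St8sia6 (-3.39 ± 0.17). Mki67 rose by 1.60 ± 0.39 (0.0179) and Notch2 fell by 0.81 ± 0.20 (0.0185), with -0.57 after quantile normalization and -0.49 with the level trend removed. Foxp3 (-0.01 ± 0.21, 0.982), Notch1 (-0.11 ± 0.19, 0.774), Notch3 (0.35 ± 0.38, 0.625) and Il2 (-0.22 ± 0.22, 0.578) did not pass.

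Cell cycle genes rose in 21 of 30 anti-CD3-CD28 Teff list members (27 adjusted over the list alone, camera adjusted p = 2.07e-17, and 0.0711 with an estimated correlation), such as Birc5 (2.91 ± 0.33), Cdk1 (2.58 ± 0.47) and Top2a (2.52 ± 0.22). Glycolysis rose in 14 of 17 (14 adjusted over the list alone, 1.61e-15, and 0.0711 with an estimated correlation), with Slc16a3 at 3.13 ± 0.19 and Hk2 at 2.99 ± 0.23, and cholesterol synthesis in 11 of 14 (12 adjusted over the list alone, 6.29e-09, and 0.0711 with an estimated correlation), with Hmgcs1 at 2.74 ± 0.29. Resting T cell genes fell in 15 of 18 (17 adjusted over the list alone, 1.57e-15, and 0.0711 with an estimated correlation), with Igfbp4 at -3.14 ± 0.33, Foxo1 at -2.46 ± 0.18 and Klf3 at -2.30 ± 0.24. Effector cytokines rose in 9 of 21 and fell in 1 (12 and 3 adjusted over the list alone, 2.18e-05, and 0.0711 with an estimated correlation), with Il4 at 3.89 ± 0.28 and Ifng at 2.60 ± 0.21. The Treg signature rose in 15 of 28 and fell in 4 (16 and 4 adjusted over the list alone, 2.08e-08, and 0.152 with an estimated correlation), with Ctla4 at 3.73 ± 0.23 and Lrrc32 at 3.52 ± 0.23. Coinhibitory receptors rose in 5 of 12 and fell in 2 (the same adjusted over the list alone, 0.00418, and 0.169 with an estimated correlation), with Havcr2 at 3.65 ± 0.26 and Tigit at 2.47 ± 0.29. The Notch pathway fell in 7 of 25 and rose in 1, Rbpj (8 and 1 adjusted over the list alone, 0.0144, and 0.0858 with an estimated correlation), falling in 4 after quantile normalization and in 2 with the level trend removed, with Dtx1 at -3.12 ± 0.20, Rbpj at 1.94 ± 0.21 and Lfng at -1.12 ± 0.22. B cell markers fell in 7 of 15 (8 adjusted over the list alone, 0.000152, and 0.0711 with an estimated correlation), the immunoglobulin segments in 19 of 19, and the Y-linked genes in 3 of 3 measured. Over all genes 1206 rose and 2163 fell (3369, and 6421 without the OX40L-JAG1 Teff arrays). With 1 array left out the count lay between 1425 genes (without control Teff replicate B) and 6421 (without OX40L-JAG1 Teff replicate B).

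Anti-CD3-CD28 Teff and OX40L-JAG1 Teff cells set the treatments side by side in effector cells. Higher with anti-CD3-CD28 were Gzmb (5.66 ± 0.26, log2, SE, n = 2 each, adjusted p = 1.1e-06), Ifi204 (5.55 ± 0.24), Il10 (4.92 ± 0.25), Gzma (4.74 ± 0.65), Il12rb2 (4.50 ± 0.28), Il13 (4.34 ± 0.34), the inhibitory receptor Tigit (4.23 ± 0.29) and Ecm1 (4.16 ± 0.22). Lower were the neutrophil and basophil genes S100a8 (-6.73 ± 0.37, 2.42e-06), Ngp (-5.74 ± 0.22), Chil3 (-5.69 ± 0.54), S100a9 (-5.55 ± 0.33), Mcpt8 (-4.95 ± 0.28), Camp (-4.92 ± 0.57), Lyz2 (-4.66 ± 0.38) and lactoferrin Ltf (-4.63 ± 0.27). All 16 passed with array weights too, with adjusted p at or below 0.000533. Mki67 (3.07 ± 0.39, 0.00037), Tnfrsf4 (2.89 ± 0.25, 3.95e-05) and Notch1 (1.2 ± 0.19, 0.00106, and 0.0489 with array weights) were higher. Notch1 had 0.32 after quantile normalization and 0.3 with the level trend removed. Foxp3 was lower (-0.93 ± 0.21, 0.00765, and 0.132 with array weights), and had -1.63 and -1.84 under these settings. Notch2 (0.49 ± 0.20, 0.0916, and -0.31 and -0.36 under these settings), Notch3 (-0.26 ± 0.38, 0.639, and -0.56 and -0.08) and Il2 (-0.55 ± 0.22, 0.082, and -0.2 and -0.17) did not pass.

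In this comparison cell cycle genes were higher in 30 of 30 (30 adjusted over the list alone, 28 with array weights, camera adjusted p = 1.45e-21, and 0.0667 with an estimated correlation), with Cenpe at 3.68 ± 0.20 and Birc5 at 3.37 ± 0.33. Glycolysis was higher in 17 of 17 (17 adjusted over the list alone, 15 with array weights, 5.05e-14, and 0.0667 with an estimated correlation) and cholesterol synthesis in 14 of 14 (14 adjusted over the list alone, 9 with array weights, 1.1e-08, and 0.0667 with an estimated correlation). The interferon response was higher in 19 of 21 (20 adjusted over the list alone, 14 with array weights, 1.34e-11, and 0.14 with an estimated correlation), with Stat2 at 2.64 ± 0.26 and Isg15 at 2.36 ± 0.30. T cell identity was higher in 6 of 12 (10 adjusted over the list alone, 2 with array weights, 8e-05, and 0.199 with an estimated correlation), with Thy1 at 1.48 ± 0.19, which had 0.59 after quantile normalization and 0.65 with the level trend removed. The NF-kappaB and TNF receptor pathway was higher in 8 of 21 (10 adjusted over the list alone, 0.00029, and 0.199 with an estimated correlation), a direction that turned in the set test after quantile normalization. In the order given, these 6 lists had 25, 14, 9, 12, 0 and 4 higher genes after quantile normalization and 23, 14, 6, 9, 0 and 3 with the level trend removed. Over all genes 4195 were higher and 2029 lower (6224), against 1302 and 125 (1427) with array weights and 1106 and 879 (1985) with the level trend removed. Of these genes 67.4% were higher, against 55% after quantile normalization and 80.4% with arrays scaled to a common median. Leaving out 1 array gave between 2666 genes (without anti-CD3-CD28 Teff replicate B) and 10906 (without OX40L-JAG1 Teff replicate 1).

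OX40L-JAG1 Treg and OX40L-JAG1 Teff cells were compared for the differences between the populations under the same treatment. Foxp3 was 18.4-fold higher in Treg cells (10.78 ± 0.20 against 6.58 ± 0.33, SD, n = 2 each, adjusted p = 4.2e-06). Socs2 was higher by 4.16 ± 0.34 (log2, SE), Il2ra by 4.04 ± 0.27, the integrin Itgae by 3.96 ± 0.18, and Lrrc32 by 3.92 ± 0.23. Tnfrsf4 was higher by 3.48 ± 0.25, the Treg transcription factor Ikzf2 by 3.39 ± 0.26 and Mbnl3 by 3.38 ± 0.33. Lower were Scarna8 (-3.70 ± 0.45), Rabggtb (-3.36 ± 0.29), Snhg17 (-2.83 ± 0.27), Nop56 (-2.76 ± 0.26), Rps20 (-2.74 ± 0.37), Ppan (-2.73 ± 0.30), Ltf (-2.57 ± 0.27) and Camp (-2.45 ± 0.57). Small nucleolar RNA genes moved with Scarna8 and Rps20, 65 of 73 being lower (42 with array weights), and neutrophil genes with Ltf and Camp, 10 of 14 being lower (6 with array weights). All 16 passed with array weights, with adjusted p from 0.000114 to 0.02. Notch2 (1.44 ± 0.20, 0.000384), Mki67 (2.44 ± 0.39, 0.000864) and Notch1 (0.91 ± 0.19, 0.00333) were higher. Notch1 had adjusted p = 0.0851 with array weights and turned to -0.12 after quantile normalization, where Notch2 had 0.45, Mki67 1.59 and Tnfrsf4 2.54. With the level trend removed these 4 genes had -0.26, 0.37, 1.19 and 2.23. Notch3 (-0.53 ± 0.38, 0.279) and Il2 (-0.37 ± 0.22, 0.192, and 0.1 after quantile normalization) did not pass.

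The Treg signature was higher in 25 of 28 in OX40L-JAG1 Treg cells (25 adjusted over the list alone, 22 with array weights, camera adjusted p = 5.85e-16, and 0.196 with an estimated correlation). The NF-kappaB and TNF receptor pathway was higher in 18 of 21 (19 adjusted over the list alone, 16 with array weights, 8.94e-11, and 0.196 with an estimated correlation), with Rel at 3.14 ± 0.21, Tnfaip3 at 2.68 ± 0.24 and Nfkb2 at 2.64 ± 0.17. The IL-2 and STAT5 response was higher in 11 of 16 (11 adjusted over the list alone, 8 with array weights, 5.38e-06, and 0.196 with an estimated correlation), with Il2rb at 2.51 ± 0.25 and Cish at 2.47 ± 0.19. Cell cycle genes were higher in 19 of 30 (19 adjusted over the list alone, 11 with array weights, 1.17e-07, and 0.246 with an estimated correlation), with Cenpe at 2.14 ± 0.20. In the order given, these 4 lists had 21, 13, 7 and 11 higher genes after quantile normalization and 21, 7, 5 and 1 with the level trend removed. Over all genes 5457 were higher and 3653 lower (9110), against 2776 and 361 (3137) with array weights and 1075 and 982 (2057) with the level trend removed. The share that was higher was 59.9%, against 79.3% with arrays scaled to a common median, and the median over all genes was -0.142 in the main test and -0.00578 after quantile normalization. With 1 array left out the count lay between 5043 genes (without OX40L-JAG1 Treg replicate B) and 12824 (without OX40L-JAG1 Teff replicate 1).

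Anti-CD3-CD28 Treg and anti-CD3-CD28 Teff cells were compared in the same way. Foxp3 was 44.3-fold higher in Treg cells (11.12 ± 0.14 against 5.65 ± 0.10, SD, n = 2 each, adjusted p = 4.72e-07). Gpr83 was higher by 4.80 ± 0.36 (log2, SE), Ikzf2 by 3.32 ± 0.26, and Zdhhc23 by 3.31 ± 0.25. Izumo1r, of the folate receptor family, was higher by 3.25 ± 0.27. The noncoding Flicr, a neighbour of Foxp3 that regulates it, was higher by 3.15 ± 0.33, Lhfp by 3.06 ± 0.24 and Gpr33 by 3.02 ± 0.21. Lower were Rps20 (-4.38 ± 0.37), Scarna8 (-4.07 ± 0.45), Ptcd3 (-4.04 ± 0.28), Wdyhv1 (-3.90 ± 0.31), Med24 (-3.79 ± 0.58), Snhg17 (-3.69 ± 0.27), the type 2 cytokine Il4 (-3.49 ± 0.28, 3.24e-05) and Ppan (-3.37 ± 0.30). Small nucleolar RNA genes moved with most of them, 69 of 73 being lower. Tnfrsf4 was higher by 1.61 ± 0.25 (0.0025). Mki67 (1.03 ± 0.39, 0.115, and 0.00034 without the OX40L-JAG1 Teff arrays), Notch1 (0.49 ± 0.19, 0.116), Notch2 (0.61 ± 0.20, 0.0731), Notch3 (-0.50 ± 0.38, 0.431) and Il2 (-0.42 ± 0.22, 0.242) did not pass. Without the OX40L-JAG1 Teff arrays, which enter this comparison only through the spread, Notch1 and Notch2 had adjusted p = 0.0358 and 0.0225, and with array weights 0.0368 and 0.0178, but their differences were 0.09 and 0.2 after quantile normalization and 0.03 and 0.17 with the level trend removed, where Mki67 had 0.55.

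The Treg signature was higher in 25 of 28 and lower in 2 in anti-CD3-CD28 Treg cells (26 and 2 adjusted over the list alone, camera adjusted p = 6.55e-21, and 0.137 with an estimated correlation). The NF-kappaB and TNF receptor pathway was higher in 14 of 21 (17 adjusted over the list alone, 2.91e-09, and 0.183 with an estimated correlation), with Rel at 2.04 ± 0.21 and Rela at 1.68 ± 0.19. The IL-2 and STAT5 response was higher in 11 of 16 (12 adjusted over the list alone, 3.34e-08, and 0.137 with an estimated correlation). Effector cytokines were lower in 8 of 21 and higher in 2 (10 and 3 adjusted over the list alone, 0.000615, and 0.183 with an estimated correlation), with Il4, Ifng at -2.20 ± 0.21 and Il10 at -1.67 ± 0.25 among them. Cell cycle genes were higher in 5 of 30 (17 adjusted over the list alone, 1.03e-06, and 0.272 with an estimated correlation), with Plk1 at 1.74 ± 0.19. With the OX40L-JAG1 Teff arrays left out 21 cell cycle genes were higher and 13 effector cytokines lower. After quantile normalization 19 Treg signature, 6 NF-kappaB and TNF receptor, 6 IL-2 and STAT5 and 2 cell cycle genes were higher, and with the level trend removed 16, 5, 4 and 2. Over all genes 2003 were higher and 642 lower (2645, and 6362 without the OX40L-JAG1 Teff arrays and 1269 with the level trend removed). The share that was higher was 75.7%, against 62% after quantile normalization and 87.4% with arrays scaled to a common median, which moved the median of all genes from -0.0467 to 0.1002. Leaving out 1 array gave between 688 genes (without anti-CD3-CD28 Treg replicate 1) and 6362 (without OX40L-JAG1 Teff replicate B).

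The interactions ask whether Treg and Teff cells responded differently to the same treatment. For OX40L-JAG1, the response of Treg cells was more positive for Car2 (4.34 ± 0.74, log2, SE, n = 2 per group, adjusted p = 0.00173), Car1 (3.83 ± 0.56), Ifi208 (3.76 ± 0.55), the stem cell factor receptor Kit (3.51 ± 0.42) and Zfp942 (3.37 ± 0.60). It was more negative for Rps20 (-5.01 ± 0.53, 0.000287), Med24 (-4.97 ± 0.82), Rabggtb (-4.84 ± 0.41), Snhg17 (-4.26 ± 0.38) and Scarna8 (-4.18 ± 0.63). Control Treg cells started near background for Car2 (4.81) and Car1 (5.01), against 9.14 and 9.69 in control Teff cells. A fall like that of Teff cells could therefore not be measured in Treg cells. Car1 had 4.77 in OX40L-JAG1 Treg cells. Car2 had 6.04 in both OX40L-JAG1 groups, and its rise in Treg cells did not pass. Neither difference shows another response. Small nucleolar RNA genes moved with Rps20, Rabggtb and Scarna8, 70 of 73 being more negative. Immunoglobulin segments were more positive in 17 of 19, after falls in 19 of 19 in Teff and 0 of 19 in Treg cells. Mki67 (2.10 ± 0.56, 0.0155), Notch2 (1.69 ± 0.28, 0.00153) and Notch1 (1.19 ± 0.26, 0.00651, but 0.01 after quantile normalization) were more positive in Treg cells. After quantile normalization Mki67 had 1.12 and Notch2 0.54, and with the level trend removed 0.65 and 0.4. Foxp3 (-0.50 ± 0.29, 0.201), Tnfrsf4 (-0.06 ± 0.36, 0.904), Notch3 (-0.71 ± 0.54, 0.322) and Il2 (0.10 ± 0.31, 0.811) did not pass. After quantile normalization Foxp3 had -1.21, Tnfrsf4 -1.05 and Il2 0.67, and with the level trend removed -1.9, -1.51 and 0.74, so these sizes depend on the scaling. Resting T cell genes were more positive in 14 of 18 (15 adjusted over the list alone, 14 with array weights, camera adjusted p = 7.33e-08, and 0.338 with an estimated correlation), as was the NF-kappaB and TNF receptor pathway in 14 of 21 (16 adjusted over the list alone, 12 with array weights, 1.58e-06, and 0.338 with an estimated correlation). After quantile normalization 8 and 5 genes of these 2 lists were more positive, and with the level trend removed 2 and 0. In all 4725 genes were more positive and 2271 more negative (6996), against 4677 with array weights and 1161 with the level trend removed. More positive were 67.5%, against 85.4% with arrays scaled to a common median, and the median of all genes was -0.174 in the main test and -0.00439 after quantile normalization. With 1 array left out the count lay between 4142 genes (without control Teff replicate B) and 12172 (without OX40L-JAG1 Teff replicate 1).

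For anti-CD3-CD28, the response of Treg cells was more positive for H2-Ab1 (3.96 ± 0.47, log2, SE, n = 2 per group, adjusted p = 0.000643), the antibody heavy chain Ighm (3.53 ± 0.27), Gpr33 (3.13 ± 0.30), Ehd3 (3.11 ± 0.35) and the metallothionein Mt2 (3.10 ± 0.56). These differences arose in different ways. H2-Ab1 had 4.24 in Treg cells (1.42e-05) and 0.27 in Teff cells (0.664), and Ighm 0.91 (0.0111) and -2.62 (1.34e-05). The other B cell markers, H2-Aa and H2-Eb1 among them, did not rise with H2-Ab1 in Treg cells. Jchain (2.89 ± 0.66) went from 5.47 to 3.5 in Treg and from 9.67 to 4.8 in Teff cells, ending below the lowest array median in both, so its difference follows the starting levels. Cd79a (1.53 ± 0.35) had -0.4 (0.416) and -1.92 (0.000469). Immunoglobulin segments, more positive in 18 of 19, fell in 8 of 19 in Treg and in 19 of 19 in Teff cells, and had been lower in control Treg than in control Teff cells in 19 of 19, with 10 of the 19 control Treg means below that median, where falls could not be measured in full. B cell markers were more positive in 3 of 15 (5 adjusted over the list alone, camera adjusted p = 0.0191, and 0.339 with an estimated correlation). The response was more negative for Med24 (-6.70 ± 0.82, 0.000826), Rps20 (-6.64 ± 0.53), Ptcd3 (-5.70 ± 0.40), Wdyhv1 (-5.43 ± 0.44) and Snhg17 (-5.12 ± 0.38), together with 70 of 73 small nucleolar RNA genes. Tnfrsf4 was also more negative (-1.93 ± 0.36, 0.0065). Foxp3 (0.77 ± 0.29, 0.109), Mki67 (0.70 ± 0.56, 0.436), Notch1 (0.77 ± 0.26, 0.0783), Notch2 (0.86 ± 0.28, 0.0697), Notch3 (-0.69 ± 0.54, 0.433) and Il2 (0.05 ± 0.31, 0.939) did not pass. Without the OX40L-JAG1 Teff arrays, which enter only through the spread, the first 4 passed, with adjusted p = 0.0219, 0.0206, 0.0208 and 0.0216, and with array weights 0.0169, 0.0453, 0.0139 and 0.0112. Their differences were 0.87, 0.57, 0.22 and 0.29 after quantile normalization and 0.05, -0.04, 0.05 and 0.17 with the level trend removed. Resting T cell genes were more positive in 13 of 18 (14 adjusted over the list alone, 4 with the level trend removed, camera adjusted p = 2.71e-09, and 0.339 with an estimated correlation), and the Treg signature more negative in 10 of 28 and more positive in 2 (13 and 5 adjusted over the list alone, 0.000409, and 0.474 with an estimated correlation). In all 2251 genes were more positive and 653 more negative (2904, and 6869 without the OX40L-JAG1 Teff arrays and 1104 with the level trend removed). More positive were 77.5%, against 56.9% after quantile normalization and 88% with arrays scaled to a common median, which moved the median of all genes from -0.0805 to 0.115. Leaving out 1 array gave between 971 genes (without control Teff replicate B) and 6869 (without OX40L-JAG1 Teff replicate B).

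Over the 22 lists and 11 comparisons, camera called 147 of 242 pairs with the preset correlation and 17 with an estimated one, and fry called 156. The mean, the median and the test differed in sign in 26 pairs, of which camera called 1, the IL-2 and STAT5 response in control Treg against control Teff cells.

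Sex-linked transcripts differed between the treatments. The mean log2 intensity of the Y-linked Kdm5d was 6.10, 7.50 and 2.65 in control, OX40L-JAG1 and anti-CD3-CD28 Treg cells and 6.29, 5.19 and 3.28 in the matching Teff cells, and that of Eif2s3y was 6.91, 8.81 and 3.73 and 6.90, 7.41 and 3.52. Xist, which silences an X chromosome in female cells, had means of 10.2, 8.54 and 11.14 in Treg and 10.75, 7.30 and 10.33 in Teff cells.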

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

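The tests of the granulocyte and Y-linked patterns were chosen only after their results were seen. Those of the small nucleolar RNA pattern were set with their bounds before, except that the requirement that a median pass its bound by more than its error was added after the values were seen.

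Treg and Teff cells differed in their response to the same treatment, as tested by the interactions. For OX40L-JAG1 6996 genes passed, 2391 after quantile normalization and 1161 with the level trend removed. Across genes the difference of the responses correlated with the mean level at 0.636, so this count depends on the scaling. The difference was positive for Car2 (4.34), Car1 (3.83), Ifi208 (3.76), Kit (3.51) and Zfp942 (3.37). Each of these 5 has a group mean below the lowest array median (4.87). Car2 and Car1 started at 4.81 and 5.01 in control Treg cells, against 9.14 and 9.69 in control Teff cells. A fall like that of Teff cells could therefore not be measured in Treg cells. Car1 had 4.77 in OX40L-JAG1 Treg cells. Car2 had 6.04 in both OX40L-JAG1 groups, and its rise in Treg cells did not pass. Neither difference shows a different response. The difference was negative for Scarna8 (-4.18), Snhg17 (-4.26), Rabggtb (-4.84), Med24 (-4.97) and Rps20 (-5.01). For anti-CD3-CD28 2904 genes passed, 1071 after quantile normalization and 1104 with the level trend removed. The difference was positive for H2-Ab1 (3.96), Ighm (3.53), Gpr33 (3.13), Ehd3 (3.11) and Mt2 (3.1). H2-Ab1 rose by 4.24 in Treg cells and had 0.27 in Teff cells. It was the only B cell marker that rose in anti-CD3-CD28 Treg cells, where H2-Aa and H2-Eb1 did not. Immunoglobulin segments did not follow it: their difference was positive in 18 of 19 because 19 of 19 fell in Teff and 8 of 19 in Treg cells, and they had been lower in control Treg than in control Teff cells in 19 of 19, where 10 of the 19 control Treg means lay below that array median. The difference was negative for Snhg17 (-5.12), Wdyhv1 (-5.43), Ptcd3 (-5.7), Rps20 (-6.64) and Med24 (-6.7).

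Granulocyte and basophil transcripts were higher in OX40L-JAG1 Treg and Teff cells, although the cells had been sorted by Foxp3 reporter after culture of CD4+ cells. In Teff cells, a trend of the change with level in the narrow range of the OX40L-JAG1 Teff arrays is argued against as the whole cause. With that trend removed 17 of 25 neutrophil and basophil genes rose, with a median of 2.12 (error 0.584), against 18 and 2.43 before. These genes are a list written after the pattern was seen, of which 3 are also in the lists fixed before. Other faults of these arrays stay open for the Teff cells. Without them 11 of 14 neutrophil genes rose in Treg cells, against 7 with them, but they enter only the spread of that comparison, so this does not test their quality. Granulocytes and basophils carried through the sort are a candidate explanation: over the 25 genes the change in Treg and in Teff cells had a rank correlation of 0.739, and genes are not independent replicates. S100a8, an abundant transcript of neutrophils, had means of 9.75 and 11.4 in the OX40L-JAG1 groups. Transcription of these genes by the T cells themselves cannot be told apart from that, since arrays do not separate cells and the median change of 12 T cell identity genes in Treg cells was -0.126. In OX40L-JAG1 Teff cells 11 of the 12 fell (median -1.54), as dilution by other cells would give. With the level trend removed 5 fell (median -0.375), but dilution may itself give that trend, so this does not tell them apart.

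Y-linked transcripts and Xist differed between the treatments. Normalization is argued against, since the mean change of 3 Y-linked genes in anti-CD3-CD28 Treg cells was -3.17 after quantile normalization. Different shares of male and female mice in the treatments cannot be told apart from other causes. With anti-CD3-CD28 the Y-linked median lay at percentile 15.7 of all genes, which only restates the pattern. Xist had 11.14 in anti-CD3-CD28 Treg against 10.2 in control Treg cells (adjusted p = 0.0521), and 10.33 against 10.75 in Teff cells (0.365). With OX40L-JAG1 Xist was lower in both cell types, at 7.3 in Teff cells. The mean Y-linked change was then 1.55 in Treg cells, as more males would give, but -0.344 in Teff cells. The labels give no sex, and no biological explanation was tested. Mice that differed would affect every comparison of treatments.

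Small nucleolar RNA genes responded to anti-CD3-CD28 in opposite directions in Treg and Teff cells. The median difference over 73 genes was -3.77, and -3.73 after quantile normalization. With anti-CD3-CD28 65 of 73 fell in Treg and 54 rose in Teff cells, and with OX40L-JAG1 29 fell in Treg and 66 rose in Teff cells (43 with array weights), so the opposite movement is not particular to anti-CD3-CD28. The control groups differed already, and this enters both responses: 32 of 73 were higher and 1 lower in control Treg than in control Teff cells, with a median of 0.836, against -2.81 between the anti-CD3-CD28 groups. A trend of the change with level is argued against as the whole cause, since 71 of the 73 passed with a negative difference after that trend was removed. An RNA preparation that kept short RNAs to a different extent is a candidate explanation, since 10 other short structured RNAs, which ranged from Rny3 (-6.37) to Rn7sk (-0.29), had a median difference of -3.6 (error 0.788), although Rn7sk, n-R5s136 (-1.41) and Rpph1 (-1.76) differed less than the others. These RNAs too were higher in control Treg cells, with a median of 1.52. A different response of Treg and Teff cells stays open and was not tested apart from the preparation.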

How the results depend on the processing

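The runs without the OX40L-JAG1 Teff arrays, with the level trend removed, and without small RNA, segment and sex-linked genes were chosen only after the results were seen. Counting each named gene in a comparison under each alternative as a result, 19831 kept their side of the threshold, 1837 fell short of it, 55 came to pass it and 19 reversed. Sign changes of genes that did not pass in the main test were not counted as reversed. One such gene is Notch2 in anti-CD3-CD28 against OX40L-JAG1 Teff cells. For lists counted in that way these counts were 5390, 250, 73 and 7. With 2 arrays per group and signal near background for dim genes, small changes are the least certain.

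Counts of genes that passed moved by more than 1.5 times as follows, and the cause was not tested unless given. With a change of at least 1 on the log2 scale, which is stricter by construction, OX40L-JAG1 Teff against control Teff cells gave 5769 genes, anti-CD3-CD28 Teff against control Teff 2016 and against OX40L-JAG1 Teff 3295, OX40L-JAG1 Treg against Teff 4880, and anti-CD3-CD28 Treg against Teff 1382. Quantile normalization gave 4823 (OX40L-JAG1 Teff against control), 3476 (anti-CD3-CD28 against OX40L-JAG1 Teff), 4013 and 1116 (OX40L-JAG1 and anti-CD3-CD28 Treg against Teff), and for the OX40L-JAG1 and anti-CD3-CD28 interactions 2391 and 1071. Array weights gave 1010 (OX40L-JAG1 Treg against control), 5450 (anti-CD3-CD28 Treg against control), 3435 (anti-CD3-CD28 against OX40L-JAG1 Treg), 4688 (OX40L-JAG1 Teff against control), 6431 (anti-CD3-CD28 Teff against control), 1427 (anti-CD3-CD28 against OX40L-JAG1 Teff), 4167 (control Treg against Teff), 3137 (OX40L-JAG1 Treg against Teff), 6113 (anti-CD3-CD28 Treg against Teff) and 7344 (anti-CD3-CD28 interaction). The 4 arrays of a comparison alone gave 771, 4705, 2771, 3524, 5638, 363, 3115, 1079 and 5131 for the first 9 of these. All rows of the table, which are more than the genes, gave 5477 (anti-CD3-CD28 Teff against control) and 4498 (anti-CD3-CD28 interaction). Without the OX40L-JAG1 Teff arrays, which widen the pooled spread, the counts were 1200, 4770 and 3082 for the Treg comparisons, 6421 for anti-CD3-CD28 Teff against control, 3220 for control and 6362 for anti-CD3-CD28 Treg against Teff, and 6869 for the anti-CD3-CD28 interaction. Removing the level trend gave 3048, 1985, 2057, 1269, 1161 and 1104 for OX40L-JAG1 Teff against control, anti-CD3-CD28 against OX40L-JAG1 Teff, OX40L-JAG1 and anti-CD3-CD28 Treg against Teff, and the interactions. List shifts fell to 17 with an estimated correlation.

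With the replicate block, counts were 306, 2124, 1258, 10411, 3240, 6059, 748, 9030 and 2471 for the 9 comparisons of 2 groups, in the order used for array weights, 6896 and 2691 for the interactions, and 148 list shifts. With each array left out in turn, where a lone array is assumed to vary like the other groups, the counts in that order ran from 99 to 1200, 1054 to 4770, 595 to 3082, 6129 to 13691, 1425 to 6421, 2666 to 10906, 248 to 3220, 5043 to 12824 and 688 to 6362, for the interactions from 4142 to 12172 and 971 to 6869, and for list shifts from 140 to 150. Of the 12 arrays, 10, 6, 6, 2, 5, 3, 6, 2 and 6 moved the count of a comparison by more than 1.5 times when left out, and 5 and 9 that of an interaction.

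Among results that passed in the main test, reversals came from quantile normalization or from removing the level trend, and the cause was not tested. Sign changes of genes that did not pass are not listed here. With quantile normalization the changes were 0.07 for Srebf2 (OX40L-JAG1 Teff against control), -0.11 for Bach2 (anti-CD3-CD28 against OX40L-JAG1 Teff), -0.12 for Notch1 and -0.24 for Slc3a2 (OX40L-JAG1 Treg against Teff), and -0.02 for Slc1a5, -0.1 for Slc3a2 and -0.12 for Ccnd3 (OX40L-JAG1 interaction). With the level trend removed they were 0.28 for Srebf2, 0.16 for Tnf and 0.07 for Nsdhl (OX40L-JAG1 Teff against control), -0.16 for Bach2 (anti-CD3-CD28 against OX40L-JAG1 Teff), -0.26 for Notch1 and -0.39 for Slc3a2 (OX40L-JAG1 Treg against Teff), and -0.05 for Shmt2, -0.22 for Cd69, -0.2 for Notch1, -0.24 for Slc1a5, -0.32 for Slc3a2 and -0.32 for Ccnd3 (OX40L-JAG1 interaction). List tests turned with quantile normalization for glycolysis (mean change 0.662) and cholesterol synthesis (0.636) in OX40L-JAG1 Teff against control, the NF-kappaB and TNF receptor pathway in anti-CD3-CD28 against OX40L-JAG1 Teff (0.0722) and in the anti-CD3-CD28 interaction (0.0635), resting T cell genes in OX40L-JAG1 Treg against Teff (-0.294), and T cell activation (0.0682) and the IL-2 and STAT5 response (0.0754) in the OX40L-JAG1 interaction.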

Other observations

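The gene groups described here were put together only after the data were seen. The bounds of the tests on host genes were set before their results, but a wider set of host genes, and the requirement that a median pass its bound by more than its error, were added after the first results were seen and left open what those had decided. The pattern tested was also set apart from the small nucleolar RNA genes after its results were seen.

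Hypoxia response genes, which are induced when oxygen is low and also by growth signals, rose in 15 of 16 in anti-CD3-CD28 Treg and in 13 of 16 in anti-CD3-CD28 Teff cells against control, and in 5 of 16 in OX40L-JAG1 Treg cells (11 without the OX40L-JAG1 Teff arrays and 10 with array weights). In OX40L-JAG1 Teff cells 4 rose and 3 fell, 1 each with array weights. Genes of fatty acid desaturation and synthesis rose in 9 of 11 in anti-CD3-CD28 Treg cells and in 3 of 11 in anti-CD3-CD28 Teff cells, and the response difference was positive in 6 of 11 (10 without the OX40L-JAG1 Teff arrays). They rose in 3 of 11 in OX40L-JAG1 Treg cells and fell in 7 of 11 in OX40L-JAG1 Teff cells, 5 with array weights. Heat shock and immediate early genes, which respond to stress within hours, fell in 5 of 18 and 6 of 18 in OX40L-JAG1 and anti-CD3-CD28 Treg cells (10 in each without the OX40L-JAG1 Teff arrays) and in 14 of 18 and 10 of 18 in the Teff cells (12 and 13 with array weights). With the level trend removed, 7 hypoxia genes rose in OX40L-JAG1 Teff cells, and 1 fatty acid gene and 8 heat shock and immediate early genes fell.

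Immunoglobulin segments, which are transcribed in B cells, were lower in control Treg than in control Teff cells in 19 of 19, and fell in 19 of 19 in both cultured Teff groups against control. In anti-CD3-CD28 Treg cells 8 of 19 fell. Histone genes rose in 16 of 47 and fell in 1 in anti-CD3-CD28 Teff cells against control, and the anti-CD3-CD28 response difference was negative in 12 of 47 (20 without the OX40L-JAG1 Teff arrays). The X-linked partners of the Y-linked genes fell in 3 of 3 in OX40L-JAG1 Teff cells against control, 2 of them with array weights and 1 with the level trend removed, and in 1 of 3 in anti-CD3-CD28 Teff cells.

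Among protein-coding genes, Med24 (-6.7), Rps20 (-6.64), Ptcd3 (-5.7) and Wdyhv1 (-5.43) led the negative response differences to anti-CD3-CD28, and Rabggtb (-4.05) was among the 20 most negative named genes. One hypothesis was that probe sets of host genes read the small nucleolar RNA inside the gene. Of the 14 protein-coding genes among those 20, 6 hold an annotated one (Med24, Rps20, Ptcd3, Wdyhv1, Ppan and Rabggtb), against 1.76% of all protein-coding genes, and so does the noncoding Snhg17. Only those in Ptcd3 and Rabggtb carry a name, so the set of named ones misses known hosts. The share with a negative difference was 9.62% of 52 hosts of the named small nucleolar RNAs against 2.19% of 18912 other protein-coding genes, a ratio of 4.38 (Fisher's exact test, two-sided, p = 0.00575). Over 333 genes with any annotated small nucleolar RNA inside, in assembly GRCm38.p6, the ratio was 2.07, between the bounds set, and the median difference of the 52 hosts was 0.314. A lower transcription of ribosomal protein genes was the other hypothesis, and 52 Rpl and Rps genes with no named small nucleolar RNA inside had a median difference of -0.417 (error 0.23), with 9 negative past the threshold. Of these 46 hold none of any name, with a median of -0.484 (error 0.189). From these values neither can be told apart from other causes.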
